A study of Homo sapiens with 16 samples.

How the data were processed

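RNA was measured in 16 libraries of PANC-1 cells, 2 in each of 8 groups set by siRNA (none, FLASH, NPAT or SLBP) and by TGFb (without or with 100 ng/ml for 48 h). The sample descriptions use the word Mock for the non-transfected cells, and the labels do not say whether these received transfection reagent. Per the labels' protocols, RNA was purified with RNeasy columns and libraries were made with the TruSeq Stranded mRNA kit, which selects poly(A) RNA. Per the submitters' processing notes, STAR 2.4.2a, RSEM 1.2.31 and GRCh38.p10 were used. The deposited table holds, for 58219 genes and each library, expected counts, which the authors obtained with these tools per the submitters' processing notes, and which share reads that map to several genes among them. Beside these the authors deposited TPM, transcript levels scaled to the same total in each library, and a transcript length per gene in bases, weighted by the share of each transcript form. No value given here rests on TPM. The deposited lengths were used only for the weighing of histone transcript forms. Values per kb for low genes rest on exon lengths from GENCODE release 29. A further 32 columns (effective length and FPKM) were not used here.

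Expected counts were first rounded to whole numbers. No count was found in any library for 26056 genes, and the 45 copies of pseudoautosomal genes on the Y chromosome are among these. The edgeR function filterByExpr kept 17743 genes, of which 17695 (99.7%) were matched by identifier to GENCODE release 29 for their positions. Library sizes were 23.8 to 30.8 M counts and were scaled by the trimmed mean of M values (TMM). Levels are given as CPM with the SD of the 2 libraries of a group.

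A negative binomial model with 1 mean per group was fitted to all 16 libraries with edgeR 4.0.16, which left 8 residual degrees of freedom. Comparisons were quasi-likelihood F tests with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The comparisons were TGFb against no TGFb in each of the 4 kinds of cells, each siRNA against non-transfected cells without and with TGFb, FLASH against NPAT and SLBP siRNA, and the interaction of each siRNA with TGFb. For gene lists, camera from limma 3.58.1 was run on voom values with a preset correlation of 0.01, and again with a correlation estimated per list. Its p values were adjusted over the lists of a comparison. Comparisons, gene lists, the rule for named genes and the alternatives were set before the data were examined.

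The 25 gene lists were written from general knowledge: replication-dependent and replication-independent histones, histone transcript processing factors, epithelial, mesenchymal, TGFb target, ID, extracellular matrix, S phase and E2F, G2 and M phase, p53, interferon, NF-kB and cytokine, apoptosis, unfolded protein and amino acid stress, cholesterol synthesis, hypoxia and glycolysis, YAP and TEAD, chromatin assembly, siRNA machinery, acinar, endocrine, leukocyte, endothelial and pericyte, and stellate and fibroblast genes. For most lists, counts of members that passed are given over all genes and adjusted over the list alone. Shares are of the members kept by the filter, which needs counts in as few as 2 libraries of any group. Members close to silent in non-transfected cells can thus enter a list only through another group, which favours rises. Of 76 replication-dependent histone, 16 endocrine, 16 leukocyte and 18 acinar genes in the table, 43, 7, 6 and 3 were tested.

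Genes were named by a fixed rule. It took the siRNA targets, the genes with the highest and lowest fold changes among those that passed with a mean of at least 5 CPM and no overlap between the groups, a fixed set of EMT genes in each comparison, the 4 members of each list with the largest change among those that passed, and the histone genes with the highest mean CPM. The text does not name every gene of these orders, and a few genes are not reported here. For all genes named as highest or lowest both libraries of one group lay beyond both of the other. Genes close to 0 counts in 1 group are given as a ratio of counts with a 95% counting interval, and genes at 0 counts as at least N-fold with a floor of 3 counts over the group. These intervals and floors cover counting error only.

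Correlations and covariances of comparisons with shared controls were set beside 20 simulations in which unchanged groups were compared with the same controls. The edgeR and camera steps were tested on simulated data made from 17174 genes. For FLASH siRNA with TGFb, 24.6% of genes changed 1.5-fold, 44.3% of genes changed 2-fold and 76.4% of genes changed 4-fold were recovered, with 4 false calls among 96. For the interaction of FLASH siRNA and TGFb the shares were 6.56%, 25.3% and 65.5%, with 4 false calls among 64. Camera called 1 of 1 shifted lists and 0 of 25 unshifted lists. The simulated genes were drawn independently, so this does not show how often camera calls unshifted lists of correlated genes.

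The alternatives were DESeq2 1.42.0, relative log expression (RLE) size factors, no filter on low counts, the replicate number as a block, a fit of only the groups compared, each library left out in turn, and the estimated correlation between genes. Nothing in the labels says that the replicates were separate cultures, so p values measure only the spread between these samples. Groups of 2 are too small to call a single library an outlier or to compare other splits of the samples. R 4.3.3, the data.table package (1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used. Raw reads, and with them the ends of transcripts, were not analysed here.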

Results

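Transcripts were sequenced in PANC-1 cells, an established human line from a pancreatic carcinoma, to ask how 3 factors of histone gene expression affect the switch between epithelial and mesenchymal states (EMT). FLASH, encoded by CASP8AP2, and the stem-loop binding protein SLBP act in the cutting of the ends of replication-dependent histone transcripts, which normally carry no poly(A) tail. NPAT activates transcription of the same histone genes. Cells were left non-transfected or received siRNA against 1 of the 3 factors, each without TGFb or with TGFb, a growth factor that drives EMT, at 100 ng/ml for 48 h. This made 8 groups of 2 libraries. Poly(A)-selected libraries held between 23.8 and 30.8 M counts each. The sample titles give day 3 and the design text gives 4 days after transfection. No group is labelled as having a non-targeting siRNA, so the uptake of any siRNA is part of each comparison of an siRNA group with non-transfected cells. The labels do not say whether these controls received transfection reagent, so its part in the comparisons is unknown.

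Between 21130 and 21355 genes had counts in each of the 4 non-transfected libraries, and between 22704 and 24368 in each of the 12 siRNA libraries. Mitochondrial genes took 6.96% to 13.1% of the counts. Across genes, log2 CPM (counts scaled to library size) of the 2 libraries of a group correlated at 0.9807 to 0.9906. The first principal component, with 39.8% of the variance, separated the non-transfected libraries, at -87.4 to -71.1, from the siRNA libraries, at -5.5 to 75.2. The second component, with 18.8%, separated libraries without TGFb, at 15.2 to 51.5, from those with TGFb, at -57.2 to -12.4.

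Each siRNA lowered its own target, with and without TGFb. CASP8AP2 (ENSG00000118412.12, GRCh38 chromosome 6, 89829894 to 89874436) was at 57.2 ± 7.39 CPM (SD, n = 2) in non-transfected cells and 11.7 ± 1.98 CPM (SD, n = 2) after FLASH siRNA, 20.5% of its level (adjusted p = 3e-06). Here and throughout, adjusted p values for genes come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. NPAT (ENSG00000149308.16, chromosome 11, 108157215 to 108222642) went from 51.2 ± 3.2 to 5.45 ± 0.0846 CPM (SD, n = 2) after its siRNA, leaving 10.7% (adjusted p = 1.2e-06). SLBP (ENSG00000163950.12, chromosome 4, 1692800 to 1712555) went from 67.4 ± 6.01 to 3.88 ± 0.501 CPM (SD, n = 2), leaving 5.76% (adjusted p = 4.1e-09). With TGFb, 21% of CASP8AP2, 12.7% of NPAT and 6.5% of SLBP remained (adjusted p = 4.3e-06, 2.5e-06 and 7.1e-09). FLASH siRNA left NPAT at 51.4 ± 6.05 CPM (SD, n = 2) and raised SLBP by 0.37 on the log2 scale, to 87.1 ± 4.18 CPM (SD, n = 2, adjusted p = 0.018). That rise missed the threshold without non-transfected replicate 2 (0.28) and without FLASH siRNA replicate 1 (0.26). CASP8AP2 stood at 45.8 ± 4.94 CPM (SD, n = 2) after NPAT siRNA (adjusted p = 0.15) and 45.4 ± 0.796 CPM (SD, n = 2) after SLBP siRNA (adjusted p = 0.14).

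**Figure D1:**
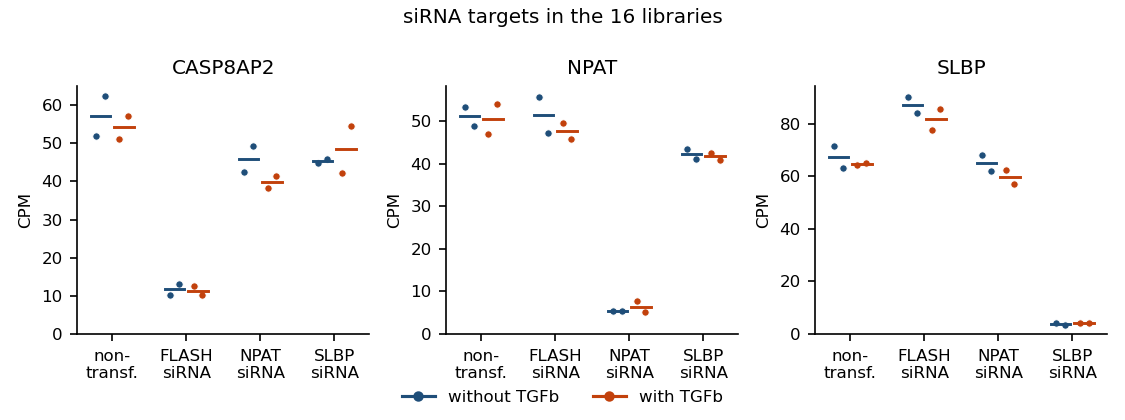
CPM of the 3 siRNA targets in each of the 16 libraries (points) with group means (short lines), without and with TGFb. Each target is lowest in the cells that received its own siRNA, for SLBP at 3.88 CPM against 67.4 CPM in non-transfected cells.

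TGFb alone moved non-transfected PANC-1 cells towards the mesenchymal state. E-cadherin (CDH1, ENSG00000039068.18, chromosome 16, 68737225 to 68835548), the adhesion protein of epithelial cells, fell from 6.28 ± 1.25 to 2.2 ± 0.0875 CPM (SD, n = 2, log2 fold change -1.51, adjusted p = 7e-04). The matrix protein fibronectin (FN1, ENSG00000115414.18, chromosome 2, 215360440 to 215436172) rose from 2.13 ± 0.331 to 16 ± 1.21 CPM (SD, n = 2, 2.91, adjusted p = 0.001). Vimentin (VIM, ENSG00000026025.15, chromosome 10, 17228259 to 17237593) rose by 1.00 to 3020 ± 300 CPM (SD, n = 2, adjusted p = 0.00032), N-cadherin (CDH2, ENSG00000170558.8, chromosome 18, 27950966 to 28177446) by 1.24 (adjusted p = 0.00084) and the EMT transcription factor SNAI1 (ENSG00000124216.3, chromosome 20, 49982999 to 49988886) by 1.59 (adjusted p = 3.8e-05). ZEB1 (ENSG00000148516.21, chromosome 10, 31318495 to 31529814), a repressor of CDH1, changed by 0.26 (adjusted p = 0.26), and SNAI2 (ENSG00000019549.9, chromosome 8, 48917604 to 48921740) had a count ratio of 10.9 (3.41 to 55.7, adjusted p = 0.13).

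Of 17743 genes tested, 1096 responded to TGFb, 805 higher and 291 lower. Among the highest fold changes were those of NKAIN4 (log2 7.66), the basement membrane collagen COL4A1 (6.25), the fibrillar collagen COL1A1 (5.49), CCM2L (5.23) and COL4A2 (4.99), with adjusted p at or below 8.4e-05. The lowest were those of AGR2 (-3.64, adjusted p = 8.3e-05), a disulfide isomerase of mucus-secreting cells, NKAIN2 (-2.38, adjusted p = 0.0022) and RASL11A (-2.08, adjusted p = 0.0018). In each of these genes both libraries of one group lay above both of the other. The count was 519 without non-transfected replicate 2, 532 without non-transfected replicate 1, and 534 and 561 without TGFb-treated replicates 1 and 2.

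Among the gene lists fixed in advance, 25 of 36 TGFb target genes rose (30 adjusted over the list alone, median 1.70), with ADAM19 at 4.79, IGFBP3 at 3.91 and PODXL at 3.88 (camera adjusted p = 9.5e-42). So did 19 of 39 mesenchymal genes (22 higher and 1 lower adjusted over the list alone, median 0.92, camera adjusted p = 1.1e-16) and 17 of 44 extracellular matrix genes (22 higher and 1 lower adjusted over the list alone, median 1.03, camera adjusted p = 9.2e-12). These 3 calls held with an estimated correlation (adjusted p = 1e-04, 0.0013 and 0.014 with an estimated correlation). Of 38 epithelial genes 6 fell (9 adjusted over the list alone, median -0.42, and -0.69 without TGFb-treated replicate 1, camera adjusted p = 1.6e-05, adjusted p = 0.24 with an estimated correlation). Replication-dependent histones had a median of 0.33 with 1 of 43 members higher (0 adjusted over the list alone), and S phase genes a median of -0.03 with a mean of 0 and 0 of 44 members past the edgeR threshold (0 adjusted over the list alone). Camera also called G2 and M phase (median -0.32), interferon (-0.76, and -0.41 without non-transfected replicate 1), ID (0.84), YAP and TEAD (0.21, and 0.12 and 0.08 without non-transfected replicate 2 and TGFb-treated replicate 1) and unfolded protein genes (0.22), with adjusted p = 1.2e-08, 3.5e-05, 0.0044, 0.0015 and 0.0051. None of these held (adjusted p = 0.64, 0.67, 0.35, 0.64 and 0.64 with an estimated correlation).

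After FLASH siRNA histone transcripts rose, as did many epithelial and mesenchymal genes, although none of the 3 list calls held with an estimated correlation (adjusted p = 0.066 for each). CDH1 rose from 6.28 ± 1.25 to 34.6 ± 5.36 CPM (SD, n = 2, log2 2.46, adjusted p = 3.4e-06), and ZEB1 fell from 68.9 ± 0.0797 to 39.8 ± 2.71 CPM (SD, n = 2, -0.79, adjusted p = 0.00033). At the same time FN1 rose to 64 ± 2.03 CPM (SD, n = 2, 4.91, adjusted p = 8.2e-06). VIM stood at 1540 ± 101 CPM (SD, n = 2, 0.02, adjusted p = 0.9) and CDH2 at 0.28 (adjusted p = 0.25). SNAI2, an EMT transcription factor like SNAI1, had a count ratio of 24.4 (counting interval 8.01 to 121, adjusted p = 0.0063, a call lost without non-transfected replicate 1 at a log2 fold change of 4.01). SNAI1 rose by 0.65 (adjusted p = 0.0057, not past the threshold at 0.56 without FLASH siRNA replicate 1).

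In all, 5989 genes differed after FLASH siRNA without TGFb, 3696 higher and 2293 lower. At 2-fold or more, 2470 were higher and 294 lower. The highest were genes close to silent in non-transfected cells. The focal adhesion protein TNS1 had a count ratio of 381 (130 to 1850), the VEGF receptor FLT1 one of 337 (92.9 to 2790), the short-chain dehydrogenase DHRS2 rose by 7.50 on the log2 scale and the cartilage matrix protein COMP had a ratio of 193 (65.7 to 939). Their adjusted p values lay at or below 2.3e-05. The lowest, besides CASP8AP2, were the ciliary gene BBS4 (-2.01, adjusted p = 0.0011) and ZFHX2-AS1 (-1.92, adjusted p = 0.00036). The count was 3772 without FLASH siRNA replicate 1 and 3931 without non-transfected replicate 1.

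Among the lists, 23 of 38 epithelial genes rose and 1 fell (the same counts adjusted over the list alone, median 1.09), including the membrane protease ST14 (5.23) and MAL2 (5.51). Their camera call (adjusted p = 3.1e-09) was lost with an estimated correlation (adjusted p = 0.066 with an estimated correlation). Of 39 mesenchymal genes 20 rose and 1 fell (21 and 1 adjusted over the list alone, median 0.77), among them FBN1, a microfibril protein, at 3.90 (camera adjusted p = 0.00015, adjusted p = 0.066 with an estimated correlation). Extracellular matrix genes rose in 32 of 44 cases (36 adjusted over the list alone, median 1.77, or 1.59 with genes at 0 counts set to their bound), with VCAN at 6.24 and COL8A1 at least 16.8-fold higher. That call held with an estimated correlation (camera adjusted p = 2.2e-11, adjusted p = 0.042 with an estimated correlation). TGFb target genes did not shift as a list (10 of 36 higher and 1 lower, the same adjusted over the list alone, median 0.24, camera adjusted p = 0.12). S phase and E2F genes rose in 28 of 44 cases and fell in 1 (29 and 1 adjusted over the list alone, median 0.55), with the nucleotide enzymes RRM2 at 1.62 and TK1 at 1.53 and the histone chaperone ASF1B at 1.67. G2 and M phase genes rose in 18 of 38 cases and fell in 1 (20 and 1 adjusted over the list alone, median 0.55), with MKI67 at 0.91 and ASPM at 0.88. Both cell cycle calls (camera adjusted p = 3.6e-07 and 2.7e-05) were lost with an estimated correlation (adjusted p = 0.47 and adjusted p = 0.53 with an estimated correlation).

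With TGFb present, FLASH siRNA again raised CDH1, from 2.2 ± 0.0875 to 18.8 ± 0.61 CPM (SD, n = 2, log2 3.09, adjusted p = 2.2e-06), and FN1, from 16 ± 1.21 to 253 ± 116 CPM (SD, n = 2, 3.98, adjusted p = 1.8e-05). SNAI2 rose by 3.13 (adjusted p = 0.0058, not past the threshold at 2.98 without non-transfected + TGFb replicate 2 or 2.69 without FLASH siRNA + TGFb replicate 2). ZEB1 fell by 0.49 (adjusted p = 0.008, and by 0.45, not past the threshold, without FLASH siRNA + TGFb replicate 2). VIM differed by -0.35 (adjusted p = 0.057), CDH2 by 0.33 (adjusted p = 0.18) and SNAI1 by 0.16 (adjusted p = 0.46). Epithelial genes rose in 27 of 38 cases (29 adjusted over the list alone, median 1.4), and the call held with an estimated correlation (camera adjusted p = 6.8e-13, adjusted p = 0.046 with an estimated correlation). So did the mesenchymal call, with 19 of 39 genes higher and 1 lower (19 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 3.5e-05, adjusted p = 0.046 with an estimated correlation). TGFb target genes had 7 of 36 higher and 6 lower (8 and 8 adjusted over the list alone), with a median of -0.13, a mean of 0.14 and a camera test pointing down (adjusted p = 0.85). S phase genes rose in 16 of 44 cases and fell in 1 (21 and 1 adjusted over the list alone, camera adjusted p = 3.5e-05, adjusted p = 0.58 with an estimated correlation).

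Altogether 4717 genes differed after FLASH siRNA with TGFb, 3109 higher and 1608 lower. The highest were the membrane peptidase DPP4 (count ratio 1060, 190 to 42000), the dynein DNAH3 (880, 157 to 34800), MYCT1 (590, 163 to 4880), CYP4F11 (279, 76.8 to 2310) and LYPD5 (log2 7.64), with adjusted p at or below 6e-05. The count was 2272 without FLASH siRNA + TGFb replicate 2 and 2582 without non-transfected + TGFb replicate 2.

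NPAT siRNA raised mesenchymal and matrix genes as well. Many epithelial genes rose and many S phase genes fell, but these 2 list calls were lost with an estimated correlation (adjusted p = 0.16 and adjusted p = 0.4). CDH1 rose to 29.5 ± 2.97 CPM (SD, n = 2, log2 2.23, adjusted p = 1.5e-05) and FN1 to 14.5 ± 3.38 CPM (SD, n = 2, 2.76, adjusted p = 0.00064). ZEB1 fell by 0.53 (adjusted p = 0.0048). CDH2 rose by 0.74 (adjusted p = 0.0075, not past the threshold at 0.64 without non-transfected replicate 1 or 0.55 without NPAT siRNA replicate 2). VIM (0.29, adjusted p = 0.095), SNAI1 (0.37, adjusted p = 0.075) and SNAI2 (count ratio 6.62, 1.95 to 34.9, adjusted p = 0.13) did not pass. PCNA, the clamp of the replication fork, fell from 118 ± 5.5 to 34.5 ± 0.391 CPM (SD, n = 2, -1.77, adjusted p = 0.00013).

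In all, 5724 genes differed after NPAT siRNA without TGFb, 3357 higher and 2367 lower, or 3248 in a fit of only the 2 groups compared. The highest were the water and glycerol channel AQP3 (log2 5.01), the hair keratin KRT81 (4.85), the collagen COL6A3 (4.84), SNCG (4.48) and the neurotrophin receptor NGFR (4.41), with adjusted p at or below 0.00062. Besides NPAT itself, the lowest included the nucleolar protein NPM1 (-2.13, adjusted p = 0.00011), ENOPH1 (-2.09, adjusted p = 0.00019) and ZNF586 (-1.94, adjusted p = 1e-04). The count was 3122 without non-transfected replicate 1 and 3735 without NPAT siRNA replicate 2.

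Epithelial genes rose in 23 of 38 cases after NPAT siRNA (26 adjusted over the list alone, median 1.04, camera adjusted p = 1.1e-06, adjusted p = 0.16 with an estimated correlation), with ST14 at 3.63 and CRB3 at 2.86. Mesenchymal genes rose in 23 of 39 cases and fell in 1 (26 and 2 adjusted over the list alone, median 1.19, or 1.06 with genes at 0 counts set to their bound), with COL1A1 at 3.35 and PDGFRB at 3.06. Extracellular matrix genes rose in 33 of 44 cases (37 adjusted over the list alone, median 1.61, or 1.56 with genes at 0 counts set to their bound). Both calls held with an estimated correlation (camera adjusted p = 2.1e-07 and 3.1e-11, adjusted p = 0.023 and adjusted p = 0.023 with an estimated correlation). Of 44 S phase genes 25 fell (26 adjusted over the list alone, median -0.53, camera adjusted p = 6e-09, adjusted p = 0.4 with an estimated correlation). Of 38 G2 and M phase genes 15 fell (15 adjusted over the list alone, median -0.42, and -0.22 without NPAT siRNA replicate 2, camera adjusted p = 1.7e-07, adjusted p = 0.51 with an estimated correlation).

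With TGFb, NPAT siRNA again raised FN1 and CDH1. Many epithelial genes rose and many S phase genes fell, with both list calls lost with an estimated correlation. It changed 4271 genes, 2436 higher and 1835 lower. CDH1 rose to 15.6 ± 0.123 CPM (SD, n = 2, log2 2.82, adjusted p = 9.7e-06) and FN1 to 67.2 ± 18.4 CPM (SD, n = 2, 2.07, adjusted p = 0.0017). SNAI1 rose by 0.52 (adjusted p = 0.021). That call was lost at 0.35 without non-transfected + TGFb replicate 1 and at 0.52 without either NPAT siRNA + TGFb library. CDH2 (0.49, adjusted p = 0.053) and ZEB1 (-0.33, adjusted p = 0.054) did not pass. The highest were LYPD5 (5.76), the collagenase MMP1 (5.52), KRT81 (4.67), NGFR (4.55) and COL6A3 (4.37), with adjusted p at or below 5e-04. Besides NPAT, the lowest included ZNF420 (-1.95), ZNF586 (-1.71) and NPM1 (-1.68), with adjusted p at or below 0.00056. Epithelial genes rose in 23 of 38 cases (24 adjusted over the list alone, camera adjusted p = 7.2e-08, adjusted p = 0.098 with an estimated correlation) and S phase genes fell in 28 of 44 (30 adjusted over the list alone, camera adjusted p = 1.8e-12, adjusted p = 0.37 with an estimated correlation). The gene count was 1668 without non-transfected + TGFb replicate 2, 1718 without NPAT siRNA + TGFb replicate 2 and 2606 without non-transfected + TGFb replicate 1.

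SLBP siRNA raised mesenchymal genes and histone transcripts, with a smaller rise of CDH1. CDH1 reached 11.7 ± 2.55 CPM (SD, n = 2, log2 0.90, adjusted p = 0.0047), a call lost at 0.69 without non-transfected replicate 1. FN1 rose to 28.2 ± 11.7 CPM (SD, n = 2, 3.73, adjusted p = 0.00013) and CDH2 from 42.4 ± 2.5 to 94.8 ± 22.5 CPM (SD, n = 2, 1.16, adjusted p = 0.00085). VIM (0.14, adjusted p = 0.41), SNAI1 (0.18, adjusted p = 0.39), ZEB1 (-0.33, adjusted p = 0.054) and SNAI2 (count ratio 9.5, 2.96 to 48.6, adjusted p = 0.068) did not pass.

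In all, 4596 genes differed after SLBP siRNA without TGFb, 2672 higher and 1924 lower. A fit of only the 2 groups compared called 529, of which 380 were higher and 149 lower. DHRS2 rose from 1.08 ± 0.622 to 771 ± 376 CPM (SD, n = 2, log2 9.48, adjusted p = 1.9e-05), the chemokine receptor CCR4 had a count ratio of 880 (158 to 34800, adjusted p = 4.8e-05) and DNAH3 rose by 7.64 (adjusted p = 1.3e-05). Besides SLBP, the lowest were ABHD10 (-2.30, adjusted p = 2.4e-06), the iron storage protein FTH1 (-2.21, adjusted p = 2e-04) and ARHGAP19 (-2.02, adjusted p = 4.1e-05). The count was 1881 without non-transfected replicate 1, 2421 without SLBP siRNA replicate 2 and 2878 without non-transfected replicate 2.

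Mesenchymal genes rose in 18 of 39 cases after SLBP siRNA and fell in 1 (22 and 3 adjusted over the list alone, median 1.07), and matrix genes rose in 29 of 44 and fell in 1 (31 and 1 adjusted over the list alone, median 1.29, or 1.24 with genes at 0 counts set to their bound). Both calls held with an estimated correlation (camera adjusted p = 1.9e-05 and 1e-09, adjusted p = 0.042 and adjusted p = 0.042 with an estimated correlation). Epithelial genes rose in 14 of 38 cases (16 higher and 1 lower adjusted over the list alone, median 0.69, camera adjusted p = 5e-04, adjusted p = 0.26 with an estimated correlation). S phase genes fell in 14 of 44 cases, SLBP itself among them, and rose in 1 (17 and 1 adjusted over the list alone, median -0.40, camera adjusted p = 6.6e-08, adjusted p = 0.34 with an estimated correlation), with the kinase CDC7 at -0.96. Of 38 G2 and M phase genes 21 fell (23 adjusted over the list alone, median -0.53, camera adjusted p = 3.8e-10, adjusted p = 0.34 with an estimated correlation), with BIRC5 at -1.18 and CKS2 at -1.11.

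With TGFb, SLBP siRNA raised mesenchymal genes on top of the TGFb response, while CDH1 did not pass. It changed 3523 genes, 2175 higher and 1348 lower. FN1 rose to 273 ± 70.1 CPM (SD, n = 2, log2 4.10, adjusted p = 3.1e-05) and CDH2 to 253 ± 31.5 CPM (SD, n = 2, 1.34, adjusted p = 3e-04), while CDH1 stood at 3.1 ± 0.36 CPM (SD, n = 2, 0.49, adjusted p = 0.13). CCR4 was at least 206-fold and the fatty acid ligase ACSBG1 at least 195-fold higher, DNAH3 had a count ratio of 1300 (233 to 51300), COL10A1 rose by 9.50 and DHRS2 by 9.34, with adjusted p at or below 5.6e-05. EPB41L4B (-2.08), FTH1 (-2.07), TINCR (-1.94) and CBX6 (-1.92) fell most after SLBP, with adjusted p at or below 0.0013. Mesenchymal genes rose in 23 of 39 cases and fell in 1 (26 and 1 adjusted over the list alone, median 0.99), a call that held with an estimated correlation (camera adjusted p = 2.1e-12, adjusted p = 0.0073 with an estimated correlation). S phase genes had 2 of 44 higher and 5 lower (the same adjusted over the list alone), with a median of 0.04, a mean of -0.08 and a camera test pointing down (adjusted p = 0.35). The gene count was 1439 without SLBP siRNA + TGFb replicate 2 and 1439 without non-transfected + TGFb replicate 2, and 2078 without non-transfected + TGFb replicate 1.

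**Figure D2:**
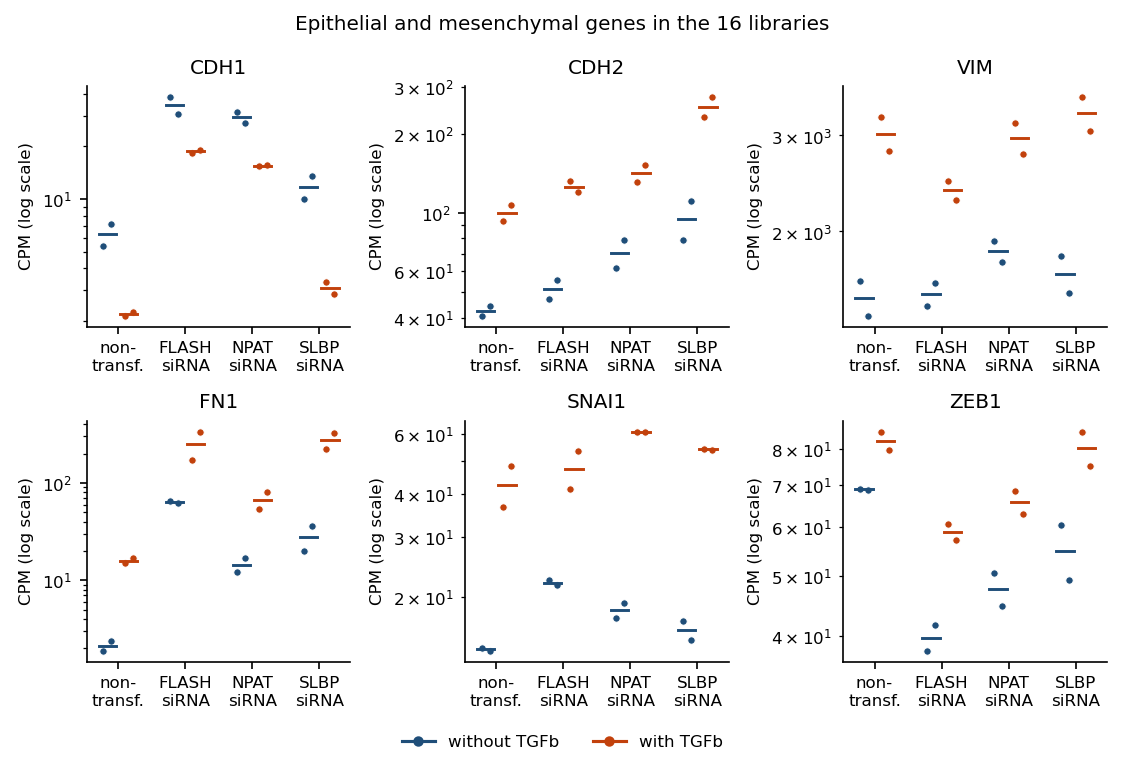
CPM (log axis) of 6 EMT genes in each of the 16 libraries (points) with group means (short lines), without and with TGFb. CDH1 rises after FLASH siRNA to 34.6 CPM without TGFb and 18.8 CPM with it, while FN1 rises after every siRNA from 2.13 CPM in non-transfected cells.

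Histone transcripts accumulated in the poly(A)-selected libraries, most after SLBP and FLASH siRNA. Summed over the 43 replication-dependent histone genes tested, the level was 118 ± 11.8 CPM (SD, n = 2) in non-transfected cells, 991 ± 15.4 CPM (SD, n = 2) after FLASH siRNA, 1260 ± 137 CPM (SD, n = 2) after SLBP siRNA and 321 ± 25.4 CPM (SD, n = 2) after NPAT siRNA. These are 8.42, 10.7 and 2.73 times the non-transfected level. HIST1H4H, a histone H4 gene, rose from 7.3 ± 0.789 to 213 ± 4.42 CPM (SD, n = 2, log2 4.87, adjusted p = 2e-07) after FLASH siRNA, by 4.92 (adjusted p = 2.8e-07) after SLBP siRNA and by 1.25 (adjusted p = 0.0018) after NPAT siRNA. The linker histone gene HIST1H1C rose by 4.55, 5.01 and 3.5 in the same order (adjusted p at or below 3.9e-06). Of the 43 genes, 34 lie on chromosome 6 between 26031650 and 27893843. Copies of a histone type are nearly identical in sequence and reads that map to several were shared out among them, so single-gene values are less certain than the sum.

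The table holds 76 replication-dependent histone genes, of which the filter kept 43, a choice that favours genes raised in an siRNA group. As a list, 40 of 43 histone genes rose after FLASH siRNA (40 adjusted over the list alone, median 3.42, or 3.19 with genes at 0 counts set to their bound), 41 after SLBP siRNA (43 adjusted over the list alone, median 3.43 or 3.35) and 24 after NPAT siRNA (28 adjusted over the list alone, median 1.33 or 1.32). The camera adjusted p values were 4.1e-20, 1.7e-28 and 7e-06, and with an estimated correlation the SLBP call held (adjusted p = 0.042 with an estimated correlation) while those of FLASH and NPAT did not (adjusted p = 0.066 and adjusted p = 0.4 with an estimated correlation). With TGFb, 34, 35 and 15 of the 43 rose after FLASH, SLBP and NPAT siRNA (39, 39 and 15 adjusted over the list alone, medians 2.60, 2.67 and 0.96). Of 10 replication-independent histone genes, 4 rose after FLASH siRNA, with H1F0 at 0.66 (adjusted p = 2e-04), 1 rose and 2 fell after NPAT siRNA, and 3 rose and 4 fell after SLBP siRNA. Adjusted over the list alone these were 4 higher, then 2 higher and 3 lower, then 3 higher and 4 lower. The list of 21 factors of histone transcript processing also holds the cell cycle genes CCNE1 and CDK2 and the transcription factor HINFP. Among its members, the U7 snRNP protein LSM11 fell after FLASH (-0.98, adjusted p = 0.0013), NPAT (-1.23, adjusted p = 0.00052) and SLBP siRNA (-1.2, adjusted p = 0.00081). The processing list had 2 higher and 6 lower, 0 higher and 7 lower, and 1 higher and 5 lower after FLASH, NPAT and SLBP siRNA (2 and 6, 0 and 9, and 1 and 5 adjusted over the list alone), with medians of -0.06, -0.22 and -0.15 (camera adjusted p = 0.14, 0.00012 and 0.01, adjusted p = 0.47, adjusted p = 0.08 and adjusted p = 0.26 with an estimated correlation). The NPAT median was -0.34 without non-transfected replicate 1, -0.14 without NPAT siRNA replicate 1 and -0.35 without NPAT siRNA replicate 2, and the SLBP median -0.09 without SLBP siRNA replicate 1.

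**Figure D3:**
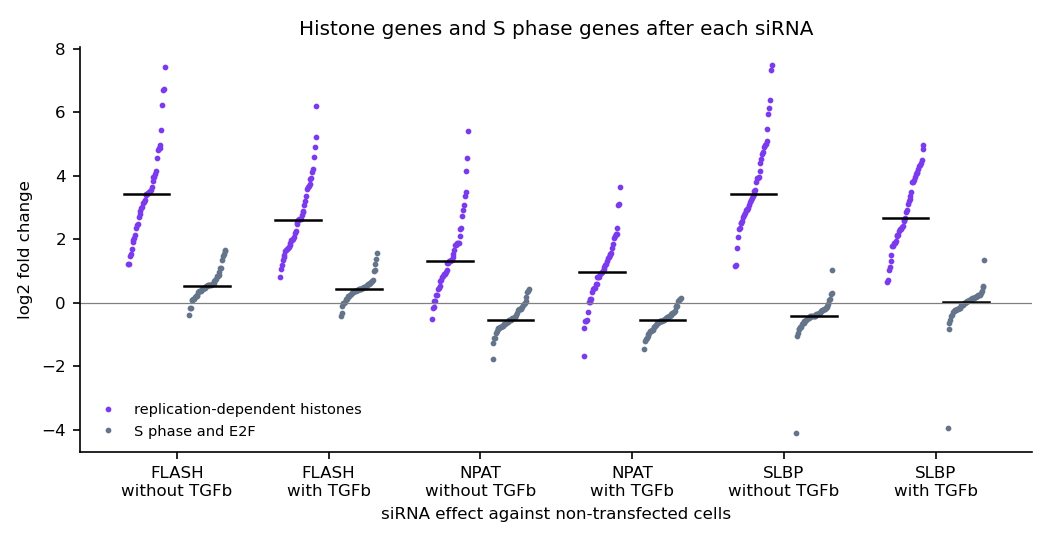
Log2 fold change of each replication-dependent histone gene and each S phase gene for the 6 siRNA effects against non-transfected cells (points), with the median of each list (short lines). The histone median is 3.42 after FLASH, 1.33 after NPAT and 3.43 after SLBP siRNA without TGFb, where the S phase medians are 0.55, -0.53 and -0.40.

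FLASH siRNA was compared directly with each of the other two, which were not compared with each other. Against NPAT siRNA, cells with FLASH siRNA had more FN1 (log2 2.15, adjusted p = 0.0016), HIST1H4H (3.61, adjusted p = 7.2e-06) and PCNA (2.25, adjusted p = 9.6e-05), with CDH1 at 0.23 (adjusted p = 0.38) and CDH2 at -0.46 (adjusted p = 0.075). Mesenchymal genes went both ways. PRRX1 was higher (3.07, adjusted p = 0.0019), while COL1A1 (-1.74, adjusted p = 0.0056) and TGFBI (-1.63, adjusted p = 5e-05) were lower. The COL1A1 call was lost at -1.59 without FLASH siRNA replicate 1 and at -1.22 without NPAT siRNA replicate 2. Of 39 members 7 were higher and 9 lower (7 and 10 adjusted over the list alone, median -0.26, camera adjusted p = 0.28). Histones were higher for 32 of 43 genes (35 adjusted over the list alone, median 1.76, camera adjusted p = 3.5e-19), S phase genes for 42 of 44 (43 adjusted over the list alone, median 1.04, camera adjusted p = 4.8e-26) and G2 and M phase genes for 35 of 38 (38 adjusted over the list alone, median 0.92, camera adjusted p = 4.1e-20), and all 3 calls were lost with an estimated correlation (adjusted p = 0.27, adjusted p = 0.27 and adjusted p = 0.42 with an estimated correlation). In all 3952 genes differed, 2194 higher and 1758 lower after FLASH siRNA. The count was 1358 without FLASH siRNA replicate 1, 1997 without FLASH siRNA replicate 2 and 2078 without NPAT siRNA replicate 2. With TGFb 2411 differed, 1612 higher and 799 lower. The number was 420 without NPAT siRNA + TGFb replicate 2, 434 without FLASH siRNA + TGFb replicate 2, 1549 without NPAT siRNA + TGFb replicate 1 and 1600 without FLASH siRNA + TGFb replicate 1. There the histone median was 1.52, with 25 of 43 genes higher (37 adjusted over the list alone, camera adjusted p = 1.6e-17, adjusted p = 0.23 with an estimated correlation). FN1 was higher there too (1.91, adjusted p = 0.0041, lost at 1.34 without FLASH siRNA + TGFb replicate 2), as was SNAI2 (2.13, adjusted p = 0.048, lost without each of the 4 libraries).

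Against SLBP siRNA, FLASH siRNA gave more CDH1, while mesenchymal genes went both ways. CDH1 was higher (log2 1.56, adjusted p = 2e-04), as were the epithelial genes MARVELD3 (2.48), OVOL1 (2.39), PKP2 (2.18) and OVOL2 (2.18), while CDH2 (-0.89, adjusted p = 0.0034) and the fibrillar collagen COL3A1 (-4.77, adjusted p = 0.00075) were lower. ZEB1 was lower too (-0.46, adjusted p = 0.012, lost at -0.42 without FLASH siRNA replicate 1 and at -0.31 without SLBP siRNA replicate 1). FN1 (1.18, adjusted p = 0.022), SNAI1 (0.46, adjusted p = 0.036) and the fibrillar collagen COL5A1 (1.51, adjusted p = 9.4e-05) were higher. The FN1 call was lost at 1.13 and 1.21 without FLASH siRNA replicates 1 and 2 and at 0.81 without SLBP siRNA replicate 1. The SNAI1 call was lost at 0.42 and 0.49 without FLASH siRNA replicates 1 and 2 and at 0.37 without SLBP siRNA replicate 2. Of 39 mesenchymal genes 11 were higher and 7 lower (13 and 9 adjusted over the list alone, median 0.07, camera adjusted p = 0.72). Epithelial genes were higher in 21 of 38 cases and lower in 2 (25 and 3 adjusted over the list alone, median 0.68, camera adjusted p = 6.4e-06, adjusted p = 0.35 with an estimated correlation). S phase genes were higher in 41 of 44 (43 adjusted over the list alone, median 0.92, camera adjusted p = 4.9e-21, adjusted p = 0.35 with an estimated correlation). SLBP is itself on that list, and its difference (4.48) comes from the siRNA against it. The histone list had 2 higher and 6 lower of 43 (median -0.15, camera adjusted p = 0.12). In all 4642 genes differed, 2720 higher and 1922 lower, or 1541 in a fit of only the 2 groups compared, 1865 without FLASH siRNA replicate 1 and 2699 without FLASH siRNA replicate 2. With TGFb the CDH1 difference was 2.60 (adjusted p = 4.6e-05) and 20 of 38 epithelial genes were higher and 1 lower (27 and 2 adjusted over the list alone, camera adjusted p = 2.9e-09, adjusted p = 0.11 with an estimated correlation). CDH2 (-1.01, adjusted p = 0.0037), VIM (-0.47, adjusted p = 0.029), ZEB1 (-0.45, adjusted p = 0.026), COL3A1 (-4.74, adjusted p = 0.0016) and CALD1 (-1.07, adjusted p = 0.0013) were lower. PRRX1 was higher (1.46, adjusted p = 0.049). The VIM and ZEB1 calls were lost without each of the 4 libraries, that of CDH2 at -0.94 without FLASH siRNA + TGFb replicate 2, and that of PRRX1 without 3 of the 4 libraries and at 1.45 with RLE factors. Of 39 mesenchymal genes 1 was higher and 8 lower (2 and 12 adjusted over the list alone, median -0.2, camera adjusted p = 0.0029, adjusted p = 0.18 with an estimated correlation). There 2311 genes differed, 1472 higher and 839 lower. This became 420 without FLASH siRNA + TGFb replicate 2, 574 without SLBP siRNA + TGFb replicate 2, 954 without SLBP siRNA + TGFb replicate 1 and 1519 without FLASH siRNA + TGFb replicate 1.

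TGFb still acted on cells that had received siRNA. CDH2 rose by 1.29 on the log2 scale in FLASH siRNA cells, 1.00 in NPAT siRNA cells and 1.42 in SLBP siRNA cells (adjusted p at or below 0.0046), and SNAI1 by 1.10, 1.73 and 1.76. CDH1 fell by 0.88 (adjusted p = 0.013), 0.92 (adjusted p = 0.0086) and 1.92 (adjusted p = 4.6e-05), and the last passed whichever library was left out. In FLASH siRNA cells the CDH1 call was lost at -0.73 without FLASH siRNA replicate 1 and at -0.85 and -0.91 without either TGFb-treated library, and in NPAT siRNA cells at -0.82 without NPAT siRNA replicate 1 and at -0.92 and -0.93 without either TGFb-treated library. Other epithelial genes went both ways. PRSS8 rose by 2.24, 2.47 and 3.24 in FLASH, NPAT and SLBP siRNA cells (adjusted p = 0.0011, 0.00048 and 7.3e-05). ELF3 fell in NPAT (-2.21, adjusted p = 0.0039) and SLBP siRNA cells (-2.08, adjusted p = 0.0045). TGFb target genes rose in 24, 22 and 28 of 36 cases in FLASH, NPAT and SLBP siRNA cells (30, 27 and 31 adjusted over the list alone, medians 1.44, 1.27 and 1.73), with adjusted p = 0.00013, 0.00023 and 3e-04 even with an estimated correlation. Mesenchymal genes rose in 18, 16 and 22 of 39 cases (23, 20 and 26 adjusted over the list alone), which also held (adjusted p = 0.00044, 0.0014 and 0.00051 with an estimated correlation).

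In FLASH siRNA cells 729 genes responded to TGFb, 595 higher and 134 lower. The numbers in NPAT siRNA cells were 946 genes, 606 higher and 340 lower, and in SLBP siRNA cells 2232 genes, 1431 higher and 801 lower. A fit of only the groups compared called 1752 genes in FLASH, 331 in NPAT and 626 in SLBP siRNA cells, so the order of these counts depends on the fit. The FLASH count was 240 and 278 without FLASH siRNA replicates 1 and 2, and 351 and 368 without FLASH siRNA + TGFb replicates 1 and 2. The NPAT count was 440 without NPAT siRNA replicate 2, and 441 and 462 without NPAT siRNA + TGFb replicates 1 and 2. For SLBP the count was 1353 without SLBP siRNA replicate 2, and 1302 and 1177 without SLBP siRNA + TGFb replicates 1 and 2.

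The interaction test asked whether the response to TGFb differed after siRNA, and edgeR called few genes. COMP responded less after FLASH siRNA (-4.53, adjusted p = 0.028), a call lost without 7 of the 8 libraries. Its level with TGFb was still higher after FLASH siRNA, at 19.5 ± 3.66 CPM (SD, n = 2), than in non-transfected cells, at 2.53 ± 0.0148 CPM (SD, n = 2). Without TGFb it was close to silent in non-transfected cells, so the smaller response is relative to a raised starting level. NKAIN4 (ENSG00000101198.14, chromosome 20, 63240784 to 63272694) rose with TGFb from 0.131 ± 0.0841 to 27.1 ± 3.63 CPM (SD, n = 2) in non-transfected cells and responded less after FLASH siRNA (-4.05, adjusted p = 0.0023) and NPAT siRNA (-4.16, adjusted p = 0.0035, lost at -3.58 without non-transfected replicate 1). In all, 15 genes passed for FLASH, 1 higher and 14 lower, 8 for NPAT, all lower, and 4 for SLBP, 2 higher and 2 lower. The counts were 157, 125 and 271 with no filter on low counts, and 31, 26 and 31 with DESeq2, where 23 were higher and 8 lower for SLBP. Unadjusted p values were under 0.05 for 597, 569 and 857 genes. The FLASH count was 7 without non-transfected replicate 1 or 2. The NPAT count was 1 and 3 without non-transfected replicates 1 and 2, and 5 without NPAT siRNA + TGFb replicate 2 or non-transfected + TGFb replicate 1. For SLBP it was 0 without non-transfected replicate 1 and between 1 and 2 without SLBP siRNA replicate 2, non-transfected replicate 2, SLBP siRNA + TGFb replicate 2 or either non-transfected + TGFb library, and 9 without SLBP siRNA replicate 1. CDH1, VIM, CDH2, FN1, ZEB1, SNAI1 and SNAI2 did not pass in any of the 3 interactions. That does not show equal responses, since 25.3% of simulated 2-fold interactions of FLASH siRNA and TGFb were recovered. The CDH1 estimates were 0.63, 0.58 and -0.41 for FLASH, NPAT and SLBP siRNA. Of the mesenchymal and matrix lists, COL5A1 (-2.14, adjusted p = 0.0019) and THBS1 (-1.74, adjusted p = 0.015) passed for FLASH siRNA. For NPAT siRNA COL5A1 (-2.09, adjusted p = 0.0035) and TGFBI (-1.25, adjusted p = 0.046) passed. With TGFb these genes still stood higher after siRNA than in non-transfected cells. COL5A1 was at 74.1 CPM after FLASH and 53.1 CPM after NPAT siRNA against 41 CPM. THBS1 was at 180 CPM after FLASH siRNA against 118 CPM, and TGFBI at 1550 CPM after NPAT siRNA against 1180 CPM. Without TGFb, COL5A1 was at 1.37 CPM in non-transfected cells, 10.9 CPM after FLASH and 7.53 CPM after NPAT siRNA. TGFBI also passed for SLBP siRNA (1.58, adjusted p = 0.011). Its calls were lost at -1.08 without NPAT siRNA + TGFb replicate 2 and at 1.42 without SLBP siRNA + TGFb replicate 2, among others.

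**Figure D4:**
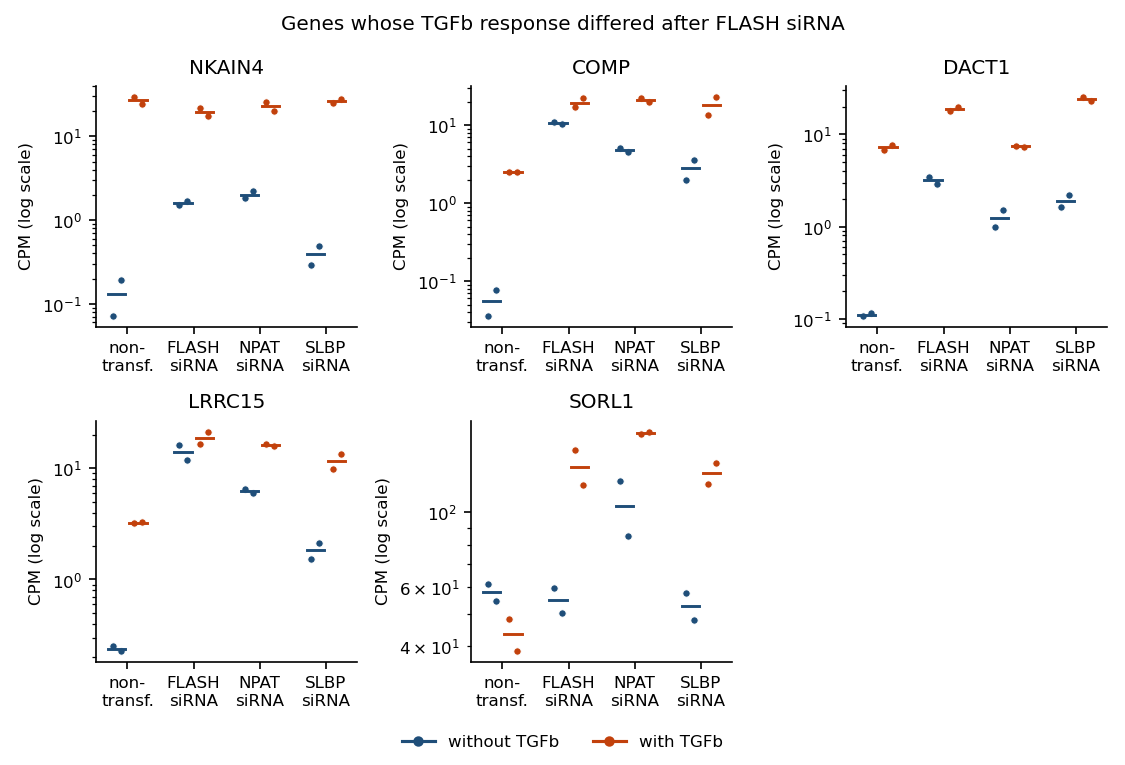
CPM (log axis) in each of the 16 libraries (points) with group means (short lines) for 5 genes whose TGFb response differed after FLASH siRNA. For NKAIN4 the level without TGFb goes from 0.131 CPM in non-transfected cells to 1.53 and 1.69 CPM after FLASH siRNA, against 27.1 CPM in non-transfected cells with TGFb.

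The 3 siRNAs moved many genes the same way. FLASH and NPAT siRNA without TGFb shared 1996 higher and 1077 lower genes, against 699 and 306 for independent lists, with 86 in opposite directions. FLASH and SLBP siRNA shared 1608 and 834 (557 and 249, 100 opposite), and NPAT and SLBP siRNA 1619 and 986 (506 and 257, 74 opposite). In all 3, 1163 genes were higher and 563 lower, with 105 and 33 for independent lists. The comparisons share the 2 non-transfected libraries. The fold changes correlated across genes at 0.82, 0.82 and 0.78 (0.49, 0.5 and 0.51 simulated), with covariances of 1.46, 1.51 and 1.1 (0.17, 0.171 and 0.174 simulated). Genes are not independent replicates, and part of the excess may come from the shared controls, which are too few to split. With the second siRNA taken from the TGFb arm, which has other controls, the correlations were 0.75, 0.77 and 0.66 and the covariances 1.31, 1.48 and 0.982.

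FLASH siRNA and TGFb had less in common. They shared 327 higher and 30 lower genes (168 and 38 for independent lists), with 162 in opposite directions. The correlation was 0.24 (0.5 simulated with the shared controls) and the covariance 0.291 (0.172 simulated). Against the TGFb response of NPAT siRNA cells, which shares no library, 257 were higher and 34 lower in both, 145 were opposite and the correlation was 0.13. The same siRNA without and with TGFb moved 4010 genes in the same direction for FLASH, 3498 for NPAT and 2468 for SLBP, with 2 opposite in each.

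Among pathways outside EMT and the cell cycle, the 3 ID genes, inhibitors of differentiation that respond to TGFb family signals, rose after each siRNA without TGFb (3 of 3 in each, also adjusted over the list alone), with ID2 at 2.92 after FLASH, 2.02 after NPAT and 2.32 after SLBP siRNA. The ID medians were 1.22, 1.15 and 1.66 (camera adjusted p = 0.085, 0.046 and 0.0063, adjusted p = 0.47, adjusted p = 0.42 and adjusted p = 0.26 with an estimated correlation). The NPAT call was lost without each of the 4 libraries, at medians from 0.96 to 1.47. With TGFb 1 of 3 rose after each siRNA. TGFb target genes rose in 11 of 36 cases after NPAT siRNA (12 adjusted over the list alone, median 0.35, camera adjusted p = 0.0041, adjusted p = 0.17 with an estimated correlation, lost at 0.26 without NPAT siRNA replicate 1). After SLBP siRNA 13 rose and 3 fell (15 and 3 adjusted over the list alone, median 0.35, camera adjusted p = 0.033, adjusted p = 0.26 with an estimated correlation, lost at 0.36 without non-transfected replicate 2 and at 0.33 without SLBP siRNA replicate 1).

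Of 27 p53 target genes, 13 rose and 2 fell after NPAT siRNA without TGFb (the same adjusted over the list alone, median 0.46, camera adjusted p = 0.034, adjusted p = 0.39 with an estimated correlation), with TP53I3 at 1.45 and CCNG1 at 1.29. The call was lost at 0.49 without non-transfected replicate 2 and at 0.33 without NPAT siRNA replicate 1. After FLASH siRNA 6 rose and 1 fell (median 0.21, camera adjusted p = 0.31), with the cell cycle inhibitor CDKN1A at 2.12 and the death receptor FAS at 1.83. After SLBP siRNA 6 rose (median 0.12, camera adjusted p = 0.41). Of 27 apoptosis regulators 8 rose and 3 fell after FLASH siRNA (10 and 3 adjusted over the list alone, median 0.17, camera adjusted p = 0.31), 7 and 4 after NPAT siRNA (median 0.13, camera adjusted p = 0.68) and 3 and 2 after SLBP siRNA, where the median was 0.06 and the mean 0.3 with a camera test pointing down (adjusted p = 0.97). BIK, a promoter of cell death, was at least 16.5-fold higher after FLASH siRNA.

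Among 37 interferon response genes, 8, 3 and 3 rose after FLASH, NPAT and SLBP siRNA without TGFb (7, 1 and 1 adjusted over the list alone), with the tetherin gene BST2 at 2.76 after FLASH siRNA. The medians were 0.68, 0.85 and 0.39 (camera adjusted p = 0.12, 0.049 and 0.048, adjusted p = 0.83, adjusted p = 0.8 and adjusted p = 0.76 with an estimated correlation), and the NPAT median was -0.05 without NPAT siRNA replicate 1. The SLBP call was lost at 0.4 without non-transfected replicate 2 and at 0.15 without SLBP siRNA replicate 1. The NF-kB targets and cytokines had 11 of 25 higher after SLBP siRNA (12 adjusted over the list alone, median 0.68, or 0.57 with genes at 0 counts set to their bound, camera adjusted p = 0.0019, adjusted p = 0.39 with an estimated correlation, lost at 0.28 without SLBP siRNA replicate 1). After FLASH siRNA 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 0.12), with PTGS2 at 3.07, and after NPAT siRNA 4 rose (median 0.44, camera adjusted p = 0.089).

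Cholesterol synthesis genes rose in 10 of 25 cases after SLBP siRNA (12 higher and 1 lower adjusted over the list alone, median 0.24, camera adjusted p = 0.0063, adjusted p = 0.26 with an estimated correlation, lost at 0.21 without non-transfected replicate 2). They had 4 higher and 2 lower after FLASH (median 0.11, camera adjusted p = 0.88) and 7 higher and 1 lower after NPAT siRNA (median 0.08, camera adjusted p = 0.71). Unfolded protein and amino acid stress genes had a median of -0.24 after SLBP siRNA, with 1 of 28 higher and 3 lower (camera adjusted p = 0.047, adjusted p = 0.6 with an estimated correlation), -0.01 after FLASH siRNA, where the chaperone HSPA5 fell by 0.73, and 0 after NPAT siRNA. The SLBP call was lost at -0.17 without non-transfected replicate 2 and at -0.01 without SLBP siRNA replicate 2. Hypoxia and glycolysis genes went both ways. The glucose transporter SLC2A3 rose by 5.07, 3.49 and 4.15 after FLASH, NPAT and SLBP siRNA, while the list medians were 0.01, -0.13 and -0.2, the last 2 with means of 0.2 and 0.1 and camera tests pointing down (adjusted p = 0.47 and 0.057).

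Chromatin assembly and heterochromatin genes had 10 of 26 higher and 1 lower after FLASH siRNA (median 0.24, camera adjusted p = 0.055), with the chromatin remodeller HELLS at 0.96. They had 0 higher and 7 lower after NPAT siRNA (median -0.13, camera adjusted p = 0.089), and 2 higher and 7 lower after SLBP siRNA (median -0.09, camera adjusted p = 0.047, adjusted p = 0.38 with an estimated correlation), with the methyltransferase DNMT1 at -0.78. This last call was lost at -0.07 without non-transfected replicate 1 and at -0.11 without SLBP siRNA replicate 1. YAP and TEAD targets had 5 of 20 higher and 1 lower, 4 and 1, and 3 and 1 (medians 0.1, 0.19 and 0.19, camera adjusted p = 0.45, 0.77 and 0.61), with the clotting initiator F3 at 1.77 after FLASH siRNA. The siRNA machinery, whose 12 genes carry out silencing, had 1 higher and 2 lower, 0 and 3, and 0 and 1 (medians -0.19, -0.21 and -0.14, camera adjusted p = 0.12, 0.07 and 0.3).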

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

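The tests of a transfection response of the same strength, of the part shared by the 3 siRNAs and of S phase, the count made in both directions over all genes and the interval between libraries were chosen after the results they weigh had been seen. The results in the next 3 paragraphs were marked because a test of the interaction found the effect of TGFb to differ between siRNA cells and non-transfected cells. The gene calls come from edgeR and the list calls from camera. The rise of low genes and of histone transcripts after siRNA, weighed after these, was not marked by that test.

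For FLASH siRNA 15 genes differed, among them COMP (-4.53), NKAIN4 (-4.05), DACT1 (-3.42), LRRC15 (-3.31) and SORL1 (1.73). The COMP and SORL1 calls were each lost without 7 of the 8 libraries, and those of DACT1 and LRRC15 without either non-transfected library (DACT1 -3.36 and -3.47, LRRC15 -3.36 and -3.25). With TGFb, COMP, DACT1 and LRRC15 stood higher after FLASH siRNA (19.5, 18.8 and 18.9 CPM) than in non-transfected cells (2.53, 7.25 and 3.24 CPM). Their smaller response is relative to a higher level without TGFb. NKAIN4 with TGFb stood at 19.8 CPM after FLASH siRNA and 27.1 CPM in non-transfected cells. Camera, which does not test the median itself, called histones (median -0.59), epithelial genes (0.15), TGFb target genes (-0.3), ID genes (-0.87), extracellular matrix (-0.38) and S phase (-0.14), with adjusted p = 3.1e-06, 0.0011, 4.3e-07, 0.00043, 1.1e-05 and 0.00098. None of these held with an estimated correlation (adjusted p = 0.43, 0.43, 0.055, 0.26, 0.13 and 0.71).

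For NPAT siRNA 8 genes differed, among them NKAIN4 (-4.16), CYP24A1 (-2.34), COL5A1 (-2.09) and TMEM92 (-2.04), of which CYP24A1 lost its call without 7 of the 8 libraries, TMEM92 without 3, and NKAIN4 and COL5A1 without non-transfected replicate 1 (-3.58 and -2). With TGFb, CYP24A1, COL5A1 and TMEM92 stood higher after NPAT siRNA (15.1, 53.1 and 25.1 CPM) than in non-transfected cells (11.2, 41 and 17.6 CPM). Their smaller response is relative to a higher level without TGFb. NKAIN4 with TGFb stood at 22.8 CPM after NPAT siRNA and 27.1 CPM in non-transfected cells. Camera called mesenchymal genes (median -0.31), TGFb target genes (-0.37), ID genes (-0.78), extracellular matrix (-0.29) and unfolded protein and amino acid stress (0.12), with adjusted p = 0.00065, 2.4e-10, 0.0063, 0.0037 and 0.011. With an estimated correlation the call of TGFb target genes held (adjusted p = 0.013) and the others did not (adjusted p = 0.12, 0.4, 0.38 and 0.89).

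For SLBP siRNA 4 genes differed, among them TGFBI (1.58) and ADM (-0.91), whose calls were lost without 5 and 7 of the libraries. Camera called histones (median -0.73), mesenchymal genes (0.17), ID genes (-1.03), S phase (0.35), unfolded protein and amino acid stress (0.37), hypoxia and glycolysis (0.15) and stellate and fibroblast genes (0.51), with adjusted p = 9.6e-07, 0.0093, 0.0011, 1.8e-13, 7.3e-06, 0.048 and 0.01. None held with an estimated correlation (adjusted p = 0.39 for the first 6 and 0.82 for the last).

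Of 4220 genes with a mean under 1 CPM in non-transfected cells, 1719, 1085 and 1007 rose at least 2-fold after FLASH, NPAT and SLBP siRNA, and 49, 43 and 36 fell, a balance that the choice of genes low in these cells favours. Over all 58219 genes, with no filter, 380, 120 and 110 lay under 1 CPM in both non-transfected libraries and at 2 CPM or more in both siRNA libraries, against 6, 7 and 6 the other way. Genomic DNA is argued against as the main source by 406 olfactory receptor genes, which were taken as silent. They gained on average at most 1.33% of the median gain of the low genes that rose (upper limit 3.77%). Per kb the shares were 4.97%, 0.568% and 5.05% for FLASH, NPAT and SLBP siRNA (upper limits 13.7%, 2.86% and 15.6%). The limit set in advance was applied without gene length, and the per-kb upper limits for FLASH and SLBP siRNA lay above it. The low genes were picked for having risen, which lowers these shares. Unspliced RNA stays open, as does scaling, since RLE factors left at least 82.2% of the 2-fold calls higher but moved that share by at most 0.5 points from TMM. Between FLASH and SLBP siRNA 1010 low genes differed at least 2-fold, 867 of them higher with FLASH siRNA. A transfection response of the same strength after each siRNA cannot, by definition, make genes differ. The test of such a response on genes picked for differing therefore decides nothing about transfection, and responses of unequal strength stay open. For the 575 genes that rose after all 3 siRNAs, transfection itself cannot be told apart from loss of the targets, because the design has no non-targeting siRNA.

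Histone transcripts rose after each siRNA, and most after FLASH and SLBP siRNA. More cells in S phase are argued against as the whole cause, since the lower quartile of the histone list lay above the upper quartile of the S phase list by at least 0.90 on the log2 scale for each siRNA. That rule was written after these results had been seen, and the filter favours histone genes raised after siRNA. It also takes both lists to follow the share of S phase cells by like folds. S phase medians were -0.53 after NPAT and -0.4 after SLBP siRNA. After FLASH siRNA the S phase median was 0.55, so a part from S phase stays open there. In the histone list, fixed in advance, 32 of 43 genes were higher after FLASH than after NPAT siRNA, with a median of 1.76 (camera call lost with an estimated correlation, adjusted p = 0.27). An equal response to transfection would give no such excess, but this says nothing about the shared part of the rise, and responses of unequal strength stay open. The rise may come from histone transcripts that gain a poly(A) tail when their ends are not cut as usual, a hypothesis on which the weighted transcript lengths were silent, with a lower median difference of 0 bases for a longer transcript form over 11 genes that went both ways (3.1 bases for FLASH siRNA, 0 bases for SLBP siRNA). Reads at transcript ends, not analysed here, would be needed to test it.

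TGFb target genes responded less after FLASH siRNA by their list median, a call lost with an estimated correlation (adjusted p = 0.055). On 507 genes chosen only in the SLBP siRNA libraries, the median TGFb effect was 1.23 in FLASH siRNA cells and 1.5 in non-transfected cells (median difference -0.27, 69% of genes lower), but genes are not independent replicates. The mean difference of these edgeR effects was -0.32. In NPAT siRNA cells the median TGFb effect on the same 507 genes was 1.31, with 67.9% of genes lower than in non-transfected cells. The TGFb target list was also lower in the NPAT interaction, where its call held with an estimated correlation. By these values the smaller response was not particular to FLASH siRNA. To show the spread between libraries, mean log2 CPM per library was used, with a prior count of 2 that shrinks changes of low genes. By this measure the difference was -0.11 (95% interval -0.31 to 0.08) for FLASH siRNA and -0.08 (-0.27 to 0.11) for NPAT siRNA. Replicate numbers were not paired. The interval belongs to the shrunken measure and gives no error for the edgeR difference, so the choice of genes as the cause stays open. On the same 507 genes the median FLASH siRNA effect was 0.9 without TGFb and 0.52 with it. For these genes, by their median, a higher starting level could account for a smaller response, with no loss of the level reached with TGFb. For the TGFb target list itself, the median FLASH siRNA effect with TGFb given above was negative and members went both ways. This reading therefore does not extend to that list. Transfection as the source of the higher starting level was not tested.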

How the results depend on the processing

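All alternatives were planned. With 2 libraries per group, leaving 1 out leaves a lone sample that is assumed to vary like the other groups, and most counts of calls fell. Without SLBP siRNA replicate 1 the count rose in 4 comparisons, from 4596 to 5501 for SLBP siRNA without TGFb, from 2232 to 2900 for TGFb in SLBP siRNA cells, from 4642 to 4700 for FLASH against SLBP siRNA without TGFb and from 4 to 9 for the SLBP interaction. For single genes that did not keep their side of the threshold, most lost it without 1 library (1465 of the comparisons of a named gene with a left-out library, against 4002 that kept it and 13 that gained it). DESeq2 kept 1266, ended 25 and added 10, RLE kept 1289, ended 17 and added 2, no filter kept 1235, ended 41 and added 32, and the fit of only the groups compared kept 1064, ended 237 and added 7. Counts of genes called kept within 1.5 times the main count in all 17 comparisons with RLE and in 14 with DESeq2.

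Called genes without 1 library ranged from 519 to 561 for TGFb in non-transfected cells (main 1096), from 3772 to 4375, 3122 to 4574 and 1881 to 5501 for FLASH, NPAT and SLBP siRNA without TGFb, and from 2272 to 3857, 1668 to 3178 and 1439 to 2560 with TGFb. They ranged from 7 to 14, 1 to 7 and 0 to 9 for the interactions of FLASH, NPAT and SLBP siRNA, from 240 to 368, 440 to 717 and 1177 to 2900 for TGFb in FLASH, NPAT and SLBP siRNA cells, from 1358 to 2869 and 1865 to 4700 for FLASH against NPAT and SLBP siRNA without TGFb, and from 420 to 1600 and 420 to 1519 with TGFb.

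With no filter on low counts, which tests more genes, 1735 genes were called for TGFb in non-transfected cells, 157, 125 and 271 for the interactions of FLASH, NPAT and SLBP siRNA, and 1490 and 1780 for TGFb in FLASH and NPAT siRNA cells. DESeq2 called 31, 26 and 31 genes for the 3 interactions, and the cause was not tested. In a fit of only the groups compared, with fewer samples, 3248 and 529 genes were called for NPAT and SLBP siRNA without TGFb, 4 and 1 for the interactions of NPAT and SLBP siRNA, 331 and 626 for TGFb in NPAT and SLBP siRNA cells, and 1541 for FLASH against SLBP siRNA without TGFb. For TGFb in FLASH siRNA cells the same fit called 1752, and the cause was not tested.

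The samples share only a replicate number. Correlations of the residuals of equal numbers over 28 pairs of groups ran from 0.05 to 0.53 (median 0.24, 25 above 0.1). With the replicate block, 2119 genes were called for TGFb in non-transfected cells, 6945 for SLBP siRNA without TGFb, 6712 and 5714 for NPAT and SLBP siRNA with TGFb, 26, 20 and 23 for the interactions, 1785, 2170 and 3915 for TGFb in FLASH, NPAT and SLBP siRNA cells, 6266 for FLASH against NPAT siRNA without TGFb, and 4652 and 4518 for FLASH against NPAT and SLBP siRNA with TGFb. Shared genes with the block were 4633, 3900 and 4310 for FLASH and NPAT, FLASH and SLBP, and NPAT and SLBP siRNA, and 694 for FLASH siRNA and TGFb. For single named genes the block kept 1285, added 23 and ended none, and CDH2 (0.49, adjusted p = 0.0045) and ZEB1 (-0.33, adjusted p = 0.014) after NPAT siRNA with TGFb were among those added. The cause was not tested.

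Of 100 list calls in the first 10 comparisons 18 held with the estimated correlation. List medians without 1 library kept their direction and call in 1828 cases, gained a call in 74, lost it in 83 and changed sign in 15, and the cause was not tested. Those that changed sign ranged from -0.05 to 1.43 (interferon, NPAT siRNA without TGFb), -0.02 or -0.13 to 0.13 (S phase, SLBP siRNA with TGFb), -0.25 to 0.33 (G2 and M phase) and -0.47 to 0.75 with 0.16 and 0.14 between (interferon) and -0.04 to 0.32 (unfolded protein) in the NPAT interaction, -0.21 or -0.05 to 0.89 (stellate, SLBP interaction), -0.01 to 0.26 (YAP, TGFb in FLASH siRNA cells), -0.53 to 0 (G2 and M phase) and -1.37 to 0.1 (interferon) for TGFb in NPAT siRNA cells, -0.92 to 0.06 (interferon, TGFb in SLBP siRNA cells) and -0.46 to 0.56 (interferon, FLASH against NPAT siRNA without TGFb). No alternative varied depth, so the limit it sets was not tested. With 2 libraries per group, 6.56% of simulated 1.5-fold and 25.3% of simulated 2-fold interactions of FLASH siRNA and TGFb were recovered.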

Other observations

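All list values in this part are of lists fixed before the data were examined, and only the count over all genes was chosen later. Some genes typical of endothelial cells, pericytes and stellate cells rose after siRNA in this carcinoma line, and no result of these 2 lists held with an estimated correlation. Over all genes, 380, 120 and 110 lay under 1 CPM in both non-transfected libraries and at 2 CPM or more in both libraries of FLASH, NPAT and SLBP siRNA, against 6, 7 and 6 the other way, so these lists were not alone. Of 11 endothelial and pericyte genes 8 rose after FLASH siRNA without TGFb (8 adjusted over the list alone), and 6 each after NPAT and SLBP siRNA (8 and 8 adjusted over the list alone), with the clotting factor carrier VWF at least 37.1-fold higher after FLASH siRNA and at least 27-fold higher after SLBP siRNA. The medians were 1.68, 2.24 and 1.89, or 1.68, 1.9 and 1.75 with genes at 0 counts set to their bound (camera adjusted p = 0.0026, 0.0023 and 0.0063, adjusted p = 0.26, 0.22 and 0.26 with an estimated correlation). Of 12 stellate and fibroblast genes 8, 4 and 7 rose (the same adjusted over the list alone), with the growth factor receptor PDGFRA at a count ratio of 89.7 (15.7 to 3580) after FLASH siRNA and the matrix protein LUM at 70.8 (12.3 to 2830) after SLBP siRNA. Their medians were 3.29, 2.25 and 2.7, or 2.42, 2.13 and 1.57 with genes at 0 counts set to their bound (camera adjusted p = 0.00095, 0.07 and 0.0019, adjusted p = 0.47, 0.67 and 0.34 with an estimated correlation).

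Pancreatic endocrine genes had 4 of 7 higher and 1 lower after FLASH siRNA, 3 higher after NPAT siRNA and 3 higher after SLBP siRNA (4 and 1, 3 and 1, and 4 and 1 adjusted over the list alone, medians 2.17, 0.9 and 0.87, camera adjusted p = 0.18, 0.26 and 0.077), with the beta cell transcription factor MAFA at 2.17 after FLASH siRNA. Leukocyte genes had 3, 2 and 1 of 6 higher (medians 1.84, 0.56 and 1.01, camera adjusted p = 0.14, 0.53 and 0.3). Of 3 acinar genes 1 rose after each siRNA (medians -0.46, 0.39 and -0.05, means 0.87, 1.14 and 1.33, camera adjusted p = 0.99, 0.82 and 0.92). The table holds 16 endocrine, 16 leukocyte and 18 acinar genes, and the filter favours those raised in an siRNA group. No source of these transcripts was tested.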
